A study of Bacillus subtilis with 24 samples.

How the data were processed

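The series holds 24 hybridisations of Bacillus subtilis RNA on 2-colour arrays in 8 groups of 3. In the Rap set, 4 strains each carried an extra copy of rapF, rapH, rapJ or rapK under an IPTG-inducible promoter. Per the labels, IPTG was added to 1 mM at an optical density near 0.5, and cells were collected 30 minutes later, when the untreated parallel culture stood near 0.8. Uninduced RNA carried Cy5 and induced RNA carried Cy3 on each of the 12 arrays, so no dye swap balances a dye effect. In the phr set, wild-type, phrC null, phrF null and phrK null cells were grown in the same minimal medium to an optical density near 1. Their RNA carried Cy5 and was hybridised against 1 pooled Cy3 reference made from exponential cells and cells entering stationary phase. The Rap arrays carried PCR products and the phr arrays carried long oligonucleotides, so the 2 sets were never put in one fit.

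The deposited values are a score per probe and array: a log ratio of the 2 channels made by the authors, with 4 decimals, whose log base is not stated. Differences are therefore given in deposited log units and no fold change is printed. The scanner, the background correction and the normalisation are not given in the sources used here. The direction of the ratio is not stated either. It is likely uninduced over induced in the Rap set, because the design has 1 gene strongly induced per strain and the probe with the lowest mean differed between strains. That probe lay below all arrays of the other strains, by 3.43 units in RapH, 3.12 in RapJ, 2.59 in RapK and 0.634 in RapF. It was the most negative probe on 8 of the 12 arrays and ranked no lower than 3 on the others. The widest gap above all other strains was 0.019 in RapH, 0.410 in RapJ and 0.325 in RapF, but 4.14 in RapK, so RapK alone would point the other way. The basis is indirect, and with the ratio turned each Rap direction turns. On the likely direction a negative Rap value means more RNA after IPTG. In the phr set the direction is unknown and was not checked on any probe. The deleted genes could not be found without gene names, and strain-specific probes were sought for this purpose in the Rap set alone. Its differences keep the deposited sign, null minus wild type or first strain minus second, and neither sign is read as more or less RNA. The Rap arrays have 4119 probes and the phr arrays have 4107, with 0 missing values and 0 per-sample columns left unused. Array medians as deposited ran from -0.163 to 0.132. The number of arrays limits the precision.

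None of the 8226 probe identifiers matched a name, locus tag or accession among the 4536 genes of the reference table used here, and the files do not pair probes with genes. No gene is named, and up to 2 positive and 2 negative probes are given per comparison. They are those with the largest change each way among probes with adjusted p under 0.05 and the same sign on each array or pair, the part of the rule for named genes that needs no gene names. The tests of gene lists, the readings of the induced rap and deleted phr genes, and the comparison of each Rap with its cognate phr deletion all need gene names and were not run.

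Each array's median was subtracted, a choice made after the medians were seen, because they were not close to 0 beside the shifts tested; values as deposited are the alternative. Relative to centred values, the deposited ones shifted the RapF response by -0.121 and the difference between RapF and RapJ by -0.157. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and a probe is called where its Benjamini-Hochberg adjusted p is under 0.05. The 12 Rap arrays entered one fit with a mean per strain, tested against 0 and against RapJ. The 12 phr arrays entered one fit with a mean per strain and the replicate number as a block, because the study describes ratios to a paired wild-type sample; that the pairs follow the replicate numbers is assumed. The design names 13 comparisons, fixed before the data were examined. Another 3, between RapF, RapH and RapK, were added afterwards, as were the probe groups defined by the RapK and RapJ responses. Those groups were tested with camera at a correlation of 0.01 and with an estimated correlation. Error is the SD over 3 arrays, or over 3 differences between arrays of equal replicate number. The Rap fit does not pair strains, so between Rap strains this matching is arbitrary and the SD is not the error tested. Per the labels' design text, replicates were independent. No pair of arrays held the same values, the highest correlation within a group being 0.903.

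The alternatives were values as deposited, arrays scaled to one median absolute deviation, robust moderation, a fit of the compared strains alone, the replicate block added or removed, and each array left out in turn. The 2 filters on missing values removed nothing. After the array correlations were seen, fits without RapF replicate 1 and RapJ replicate 1 were added. The fit was tested on simulated data with the spread of the real probes and 200 changed probes. Changes of 1 unit were recovered for 99.5 to 100% of probes in the 4 tests against 0 and for 96.5 to 98% in the 3 tests against wild type. Changes of 0.5 units were recovered for 84.5 to 89% and 70.5 to 76%, and for 27.5 to 37.5% in the 3 differences from RapJ. These shares hold for 200 changed probes and the same spread in all strains. With fewer changed probes the adjusted threshold is stricter, so few calls do not show that few probes moved by 0.5 units. In the real data WGD8-878 was not called at -0.909 in RapH (limma adjusted p = 0.0529). Nor was WGD8-1116 at 0.723 in RapF (limma adjusted p = 0.0532).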

Results

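Transcript ratios were measured for 4119 probes on 12 arrays of 4 rap strains and for 4107 probes on 12 arrays of 3 phr null strains and wild type, with 3 arrays per strain. Rap proteins are regulators of signalling proteins such as ComA and Spo0F, and Phr peptides are secreted signals that inhibit Rap proteins. Pearson correlations across probes between arrays of one strain ran from 0.645 to 0.736 in RapK, from 0.355 to 0.476 in RapH, from 0.155 to 0.76 in RapJ and from 0.13 to 0.622 in RapF. In the phr set they ran from 0.833 to 0.903 in phrF null, from 0.769 to 0.873 in phrC null, from 0.514 to 0.858 in phrK null and from 0.333 to 0.552 in wild type. Some Rap arrays were nearer to another strain than to their own. RapJ replicate 1 had r of 0.464 with RapH replicate 2, against 0.155 and 0.317 with RapJ replicates 2 and 3. For RapF replicate 1 it was 0.377 with RapH replicate 3, against 0.13 and 0.214 with RapF replicates 2 and 3. Probes are not independent replicates.

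**Figure D1:**
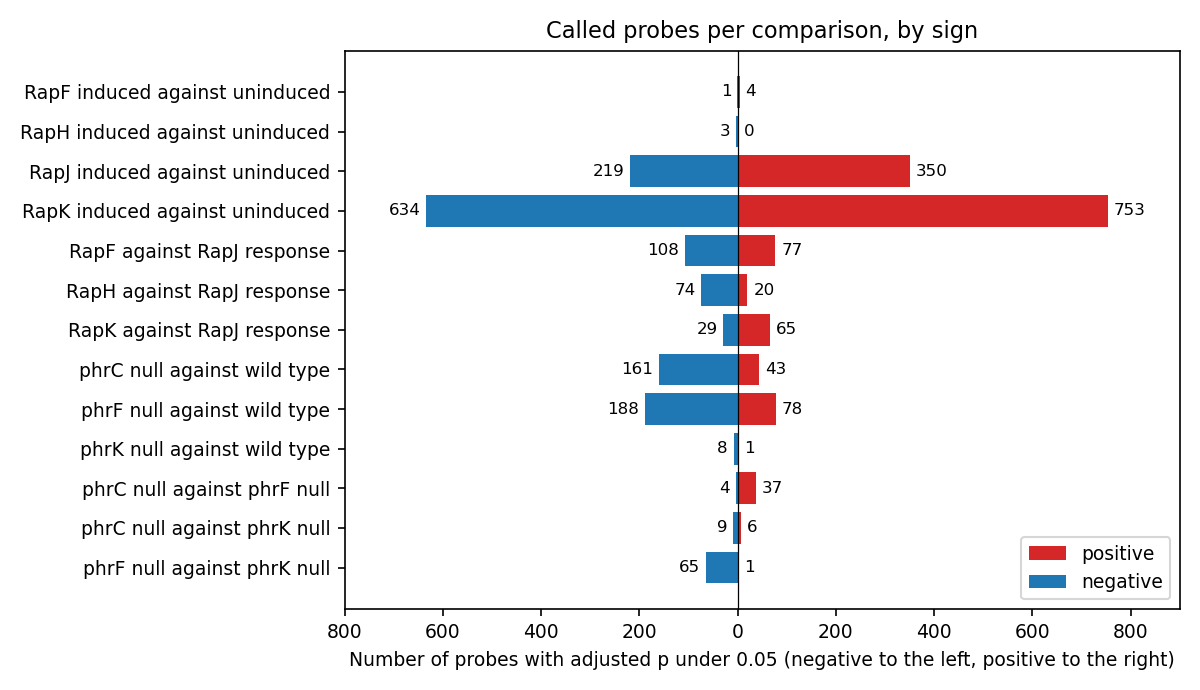
Number of probes with adjusted p under 0.05 in each of the 13 comparisons, positive values to the right and negative values to the left. RapK had the most called probes, 753 positive and 634 negative, and RapH had 3, all negative.

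Which transcripts change when RapK is induced? The RapK response had the most called probes of the 4 strains, 1387, of which 753 were positive and 634 negative. In size it was dominated by a few positive probes: 37 called probes were at 1 unit or more and 8 at -1 unit or less, and the median size of a called change was 0.441. Probe WGD8-1116 was at 5.21 ± 0.257 (SD, n = 3; limma adjusted p = 8.28e-13) and WGD8-770 at 5.02 ± 0.0859 (SD, n = 3; limma adjusted p = 3.56e-13). On the likely direction, these RNAs were less abundant after induction. The most negative probes were WGD8-887 at -3.24 ± 0.314 (SD, n = 3) and WGD8-6 at -1.70 ± 0.154 (SD, n = 3). Positive probes were 54.3% of those called, and 66.4% without centring. Without RapK replicate 2 the count was 880, with arrays scaled to one spread 698, and in a fit of the RapK arrays alone 819.

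The RapJ arrays gave 569 called probes, 350 positive and 219 negative, of which 24 were at least 1 unit in size. The most negative was WGD8-886 at -3.80 ± 0.216 (SD, n = 3; limma adjusted p = 2.39e-12), followed by WGD8-6 at -1.99 ± 0.379 (SD, n = 3). The most positive were WGD8-3961 at 2.02 ± 0.803 (SD, n = 3) and WGD8-4112 at 1.92 ± 0.335 (SD, n = 3). The count rested on single arrays: it was 1092 without RapJ replicate 1, 263 without replicate 2 and 132 without replicate 3. It was 249 with arrays scaled to one spread, 179 of them positive, and 107 in a fit of the RapJ arrays alone.

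Induction of RapH gave 3 called probes, all negative in the fit of the 4 strains. WGD8-884 stood at -3.95 ± 0.0848 (SD, n = 3; limma adjusted p = 4.24e-10), while its mean in the other 3 strains lay between 0.00313 and 0.263. WGD8-1566 was at -0.708 ± 0.108 (SD, n = 3; limma adjusted p = 0.0497) and was no longer called as deposited, where its adjusted p was 0.0632, nor without any one of the RapH arrays. An unadjusted p under 0.05 was found for 734 probes. Both the count and the signs depended on the setting: 221 probes were called in a fit of the RapH arrays alone, 82 of them positive, and 399 with arrays scaled to one spread, 122 of them positive. The count was 8 with robust moderation, all negative, and 1 without RapH replicate 1, 2 or 3.

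With RapF, 5 probes were called, 4 positive and 1 negative. The negative probe was WGD8-882 at -1.34 ± 0.015 (SD, n = 3; limma adjusted p = 6.25e-05). WGD8-770 was at 0.936 ± 0.305 (SD, n = 3) and WGD8-879 at 0.886 ± 0.0759 (SD, n = 3), each with a limma adjusted p of 0.000956. An unadjusted p under 0.05 was found for 507 probes. The count was 382 with arrays scaled to one spread, 252 of them positive, 9 with robust moderation, 2 in a fit of the RapF arrays alone, with WGD8-770 not among them, 10 without RapF replicate 1, and 3 without replicate 2 or replicate 3.

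**Figure D2:**
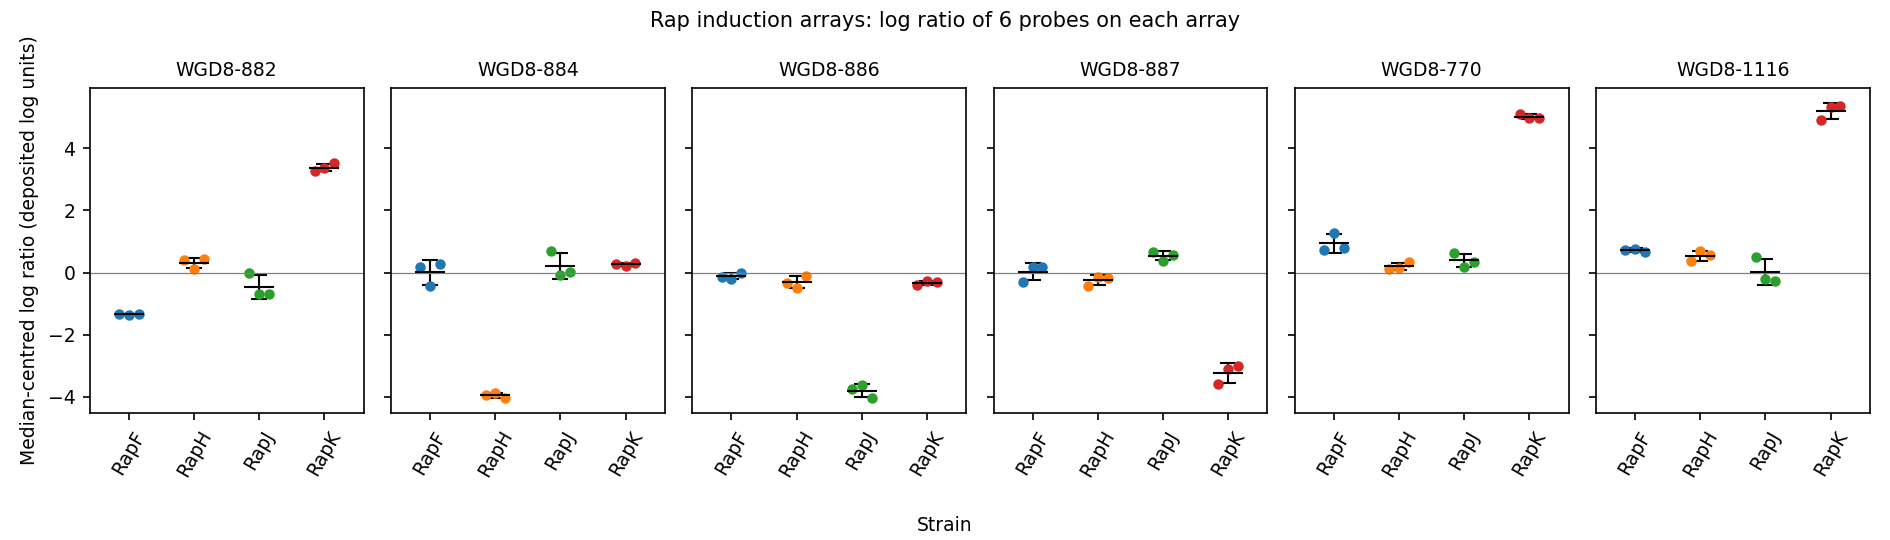
Median-centred log ratio, in deposited log units, of 6 probes in the 4 rap strains. Points are single arrays, dashes are means and bars are SDs over 3 arrays. WGD8-882, WGD8-884, WGD8-886 and WGD8-887 each lie lowest in 1 strain, a different one for each, and WGD8-882 is at 3.38 in RapK against -1.34 in RapF.

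Did the strains move the same probes? Of the 4 probes called positive in RapF, 3 were also called positive in RapK, where 0.731 would be shared by independent lists (Fisher's exact test, adjusted p = 0.108). The 9 probes at 2 units or more in RapK, 1 of which was WGD8-882 and called negative in RapF, had a median of 0.590 in RapF, 0.309 in RapH and 0.012 in RapJ. Set against the other probes with camera at the preset correlation, they were higher in RapF (adjusted p = 6.34e-08) and in RapH (adjusted p = 2.1e-05), and not in RapJ (adjusted p = 0.771). With an estimated correlation neither call held (adjusted p = 0.119 in both). The wider group of 37 probes at 1 unit or more in RapK was higher in RapJ too (adjusted p = 4.89e-05), with a median of 0.106 and quartiles of -0.033 and 0.810, and 12 of them were called positive there and 2 negative. That call also ended with an estimated correlation (adjusted p = 0.19). RapJ and RapK shared 233 positive calls, against 64 for independent lists, and 135 negative calls, against 33.7 (Fisher's exact test over probes, which are not independent; adjusted p = 6.8e-98 and 6.48e-58). Over the 233 shared positive probes the median was 0.444 in RapJ, 0.493 in RapK, 0.166 in RapH and -0.0077 in RapF.

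Since all 4 strains received IPTG with the same dye order, subtracting the RapJ response removes what IPTG or a dye does alike in both. The subtraction does not remove the inserted gene itself, which WGD8-884, WGD8-886 and WGD8-887, the lowest probes of RapH, RapJ and RapK, may report. RapK and RapJ differed at 94 probes, 65 with a higher value in RapK and 29 with a lower one. The difference was 5.20 ± 0.679 (SD, n = 3) at WGD8-1116, 4.63 ± 0.147 (SD, n = 3) at WGD8-770 and -3.78 ± 0.422 (SD, n = 3) at WGD8-887. The lower calls were the less stable: 9 of 59 calls were lower without RapJ replicate 3, 6 of 52 without RapK replicate 2, 3 of 35 with arrays scaled and 1 of 31 in a fit of these strains alone. Without RapK replicate 3 there were 143 calls, 56 of them lower.

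RapF and RapJ differed at 185 probes, 77 higher in RapF and 108 lower, and 13.4% were higher without centring against 41.6% with it. WGD8-886 was higher in RapF by 3.68 ± 0.311 (SD, n = 3), and WGD8-4112 differed by -2.002 ± 0.405 (SD, n = 3). RapH and RapJ differed at 94 probes, 20 higher in RapH and 74 lower, with WGD8-884 at -4.16 ± 0.431 (SD, n = 3) and WGD8-886 at 3.49 ± 0.412 (SD, n = 3). Both counts moved with single arrays of either strain. The balance of signs moved as well. Without RapJ replicate 1 the counts were 1010 for RapF, 501 of them higher, and 524 for RapH, 241 of them higher. Without RapJ replicate 2, 20 of 90 and 4 of 62 were higher, and without replicate 3, 7 of 37 and 2 of 26. Leaving out RapF replicate 1, 2 or 3 gave 108, 52 and 65, of which 50, 15 and 19 were higher in RapF, and leaving out RapH replicate 1, 2 or 3 gave 21, 36 and 33, of which 2, 5 and 3 were higher in RapH. With arrays scaled to one spread most RapF calls were higher, 158 of 288, and in fits of the compared strains alone 12 of 47 and 3 of 31 were higher.

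What does loss of each Phr peptide change? The direction of the phr ratio is not known, so differences are given with the deposited sign, null minus wild type, and with the ratio turned each sign turns. In phrF null cells 266 probes were called against wild type, 188 negative and 78 positive, and 62 of the negative ones but 2 of the positive ones were at least 1 unit in size. BSO2-1326 differed by -4.79 ± 0.240 (SD, n = 3; limma adjusted p = 2.16e-09) and BSO2-909 by -4.77 ± 0.224 (SD, n = 3; limma adjusted p = 1.04e-08). The most positive differences were 1.10 ± 0.666 (SD, n = 3) at BSO2-545 and 1.07 ± 0.757 (SD, n = 3) at BSO2-1620. The call at BSO2-1620 ended without the replicate block (adjusted p = 0.0779), and both ended without phrF null replicate 1 or 3. BSO2-1620 was also not called without wild-type replicate 3 or with arrays scaled, and neither was called in a fit of these strains alone. The positive calls varied with the arrays used: 24 of 171 calls were positive without phrF null replicate 1, 48 of 185 without replicate 2 and 3 of 117 without replicate 3. Without wild-type replicate 1 they were 29 of 206, without wild-type replicate 2 they were 115 of 268, without wild-type replicate 3 they were 62 of 250, with arrays scaled 37 of 204, and in a fit of these strains alone 1 of 82.

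In phrC null cells 204 probes were called, 161 negative and 43 positive. BSO2-216 differed by -3.20 ± 0.359 (SD, n = 3; limma adjusted p = 0.00745) and BSO2-217 by -2.98 ± 0.412 (SD, n = 3; limma adjusted p = 0.00204). The most positive differences were 1.34 ± 0.432 (SD, n = 3) at BSO2-988 and 1.09 ± 0.149 (SD, n = 3) at BSO2-2625. Positive probes were 21.1% of those called, and 45.2% without centring. Without phrC null replicate 2, 19 of 121 calls were positive, without replicate 3 10 of 112, without wild-type replicate 2 30 of 134, and in a fit of these strains alone 7 of 66.

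In phrK null cells 9 probes were called, 8 negative and 1 positive, and 611 had an unadjusted p under 0.05. BSO2-1576 differed by -1.12 ± 0.311 (SD, n = 3; limma adjusted p = 0.00504), BSO2-1055 by -1.09 ± 0.154 (SD, n = 3; limma adjusted p = 0.00127) and BSO2-936 by 0.831 ± 0.239 (SD, n = 3; limma adjusted p = 0.0438). Without the replicate block 3 probes were called, and BSO2-1576 and BSO2-936 were not among them. In a fit of these strains alone none of the 3 named probes was called (adjusted p = 0.0516 for BSO2-1055, 0.0824 for BSO2-1576 and 0.122 for BSO2-936). BSO2-936 was also not called without phrK null replicate 1, 2 or 3 or without wild-type replicate 2 or 3. The count was 2 without phrK null replicate 1 or 2, 3 without wild-type replicate 2, and 32 without wild-type replicate 1. It was 26 as deposited, 19 with arrays scaled and 2 in a fit of these strains alone.

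**Figure D3:**
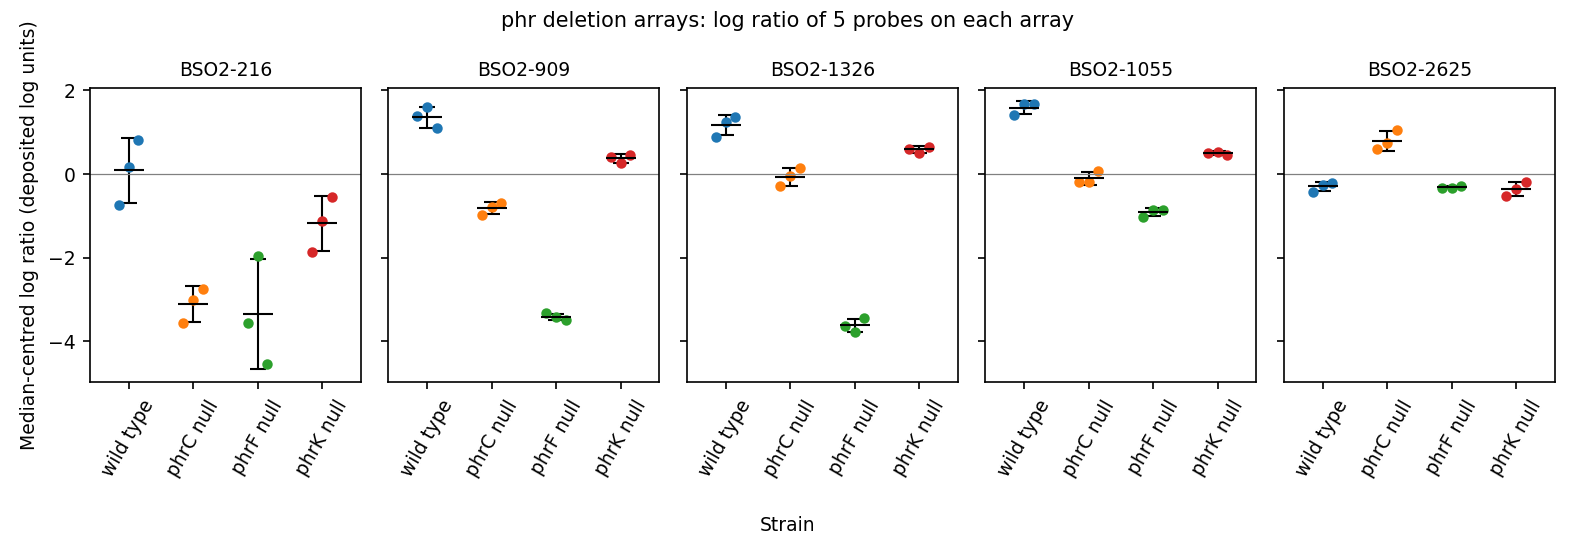
Median-centred log ratio against the reference pool, in deposited log units, of 5 probes in wild type and 3 phr null strains. Points are single arrays, dashes are means and bars are SDs over 3 arrays. BSO2-1326 and BSO2-909 have negative ratios in phrF null, at -3.62 and -3.41, and BSO2-2625 a positive one in phrC null, at 0.797.

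The phrC null and phrF null lists overlapped: 125 probes were negative in both, against 7.37 for independent lists, and 14 were positive in both, against 0.817. Both comparisons use the same 3 wild-type arrays. In 100 simulations of unchanged strains against shared wild-type arrays, 0 probes were called in both. The correlation of the differences across probes was 0.819, against 0.502 simulated, and the covariance was 0.0901, against 0.00987 simulated. Values for phrK null, which had 9 called probes, also lay above the simulated ones. Its correlation was 0.638 with phrC null and 0.596 with phrF null, against 0.497 and 0.498 simulated. Its covariance was 0.0433 and 0.0533, against 0.00966 and 0.00978. Spearman's rho was 0.743 and 0.782 against 0.746 for phrC null and phrF null, and the same sign was found at 78.9%, 80.4% and 77.9% of probes, against 66.7 to 66.8% simulated. The simulations gave all strains the same spread per probe. The median SD over probes was in fact 0.163 in wild type and 0.0896 to 0.0996 in the null strains. A more variable shared wild type raises the correlation, the covariance and the same-sign share of unchanged strains, and can raise their shared calls. The simulated values are therefore likely too low, and how much of each gap a shared change accounts for cannot be told. With 3 wild-type arrays no split leaving a pair in each part was possible, and part of each gap may come from the shared arrays.

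With all arrays kept, the estimated differences between the null strains do not use the wild type. Their called counts and adjusted p-values do, because the wild-type arrays enter the error of the joint phr fit. Only the fits of the compared strains alone leave the wild type out. The phrC and phrF null strains differed at 41 probes, 37 of them with a lower ratio in phrF null, BSO2-1326 differing by 3.55 ± 0.187 (SD, n = 3) and BSO2-1325 by 3.43 ± 0.059 (SD, n = 3). The count was 25 without phrC null replicate 2 or 3 or phrF null replicate 3, 23 without phrF null replicate 2 and 23 in a fit of these strains alone. The phrF and phrK null strains differed at 66 probes, 65 of them with a lower ratio in phrF null, with BSO2-1326 at -4.21 ± 0.0887 (SD, n = 3). The phrC and phrK null strains differed at 15 probes, 6 with a higher ratio in phrC null and 9 with a lower one, with BSO2-2625 at 1.15 ± 0.0677 (SD, n = 3) and BSO2-909 at -1.19 ± 0.174 (SD, n = 3). As deposited 8 of 15 were higher in phrC null, and with arrays scaled 9 of 16. BSO2-909 was not called with arrays scaled (limma adjusted p = 0.0719). The count was 9 without phrC null replicate 1, 8 without phrK null replicate 1 or 2, 25 without phrK null replicate 3 and 56 in a fit of these strains alone.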

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

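The comparisons between RapF, RapH and RapK, the tests of the RapJ and RapK probes in RapF, and the test on the other phr strains were chosen after the results were seen. Strains given the same treatment differed in their measured response, by tests of the difference itself. These tests take the replicates of a strain as interchangeable, which the Rap arrays were not in full. RapJ replicates 2 and 3 had r of 0.462 to 0.503 with RapK arrays, against 0.045 to 0.234 for RapJ replicate 1. Whether differences between cultures or hybridisations add to the Rap counts was not tested. RapF and RapJ differed at 185 probes, RapH and RapJ at 94, RapK and RapJ at 94, RapF and RapH at 2, RapF and RapK at 661 and RapH and RapK at 411. Among the null strains, phrC and phrF differed at 41 probes, phrC and phrK at 15 and phrF and phrK at 66. WGD8-882 went opposite ways, at -1.34 in RapF and 3.38 in RapK, a difference of -4.72 (limma adjusted p = 2.53e-10; same direction in 3 of 3 differences). WGD8-887 was at -3.24 in RapK and 0.543 in RapJ, a difference of -3.78 (limma adjusted p = 1.67e-09; 3 of 3 differences). WGD8-882 and WGD8-887 were the lowest probes of RapF and RapK, used above to read the direction. They may report the inserted rap gene itself, so these low values need not be a response to the Rap protein. Groups of 3 arrays were too small for a search for outlying arrays.

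RapJ and RapK shared 368 probes called the same way, which an effect of IPTG or of the dyes common to the 4 strains would move alike in each. Turned to their shared sign, their median was 0.424 in RapJ and 0.48 in RapK but 0.00348 in RapF, with an upper quartile of 0.107, which argues against it as the whole cause. In RapH the median was 0.162, with 313 of the 368 probes of the shared sign, so a common effect on part of the response stays open. A state carried by RapJ replicates 2 and 3 alone stays open: over probes called in RapK, the median was 0.082 in RapJ replicate 1, against 0.304 and 0.321 in replicates 2 and 3, and lay between the bounds set in advance. Over the same probes it was 0.0725 to 0.0996 on the RapH arrays and -0.0131 to 0.0291 on the RapF arrays. By this measure RapJ replicate 1 was no nearer to RapK than the RapH arrays were. A target that RapJ and RapK share was not tested and also stays open.

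Pearson correlations over all probes did not group the phrK null and wild-type arrays by strain. There r was 0.858 between phrK null replicates 1 and 2, but 0.835 between phrK null replicate 1 and wild-type replicate 1. It was 0.818 between phrK null replicate 3 and wild-type replicate 2. By Spearman's rho phrK null replicate 3 was nearer to phrK null replicate 2, at 0.787, than to wild-type replicate 2, at 0.751. Wild-type replicate 1 was still nearer to phrK null replicate 1, at 0.786, than to wild-type replicate 2, at 0.663. An exchange of labels between phrK null replicate 3 and wild-type replicate 1 predicted that phrK null replicates 1 and 2 with wild-type replicate 1 would have the probe lying furthest from the other arrays, and among 20 sets of 3 they did, at 2.89 units, while the arrays labelled phrK null ranked 3 at 0.437. Against an exchange, the 3 arrays labelled wild type ranked 2 at 0.877, at BSO2-1055, and had the most probes apart from all other arrays, 228, while the set an exchange would make wild type ranked 4 at 0.402 and had 128; the counts for phrK null, 28 as labelled and 84 exchanged, go the other way. A difference between cultures, such as growth stage, could give the same ranking. The leading axis of the replicate deviations of these 6 arrays, 54.3% of their variance, had correlations of up to 0.409 in size with phrC null deviations and 0.181 with phrF null deviations, which leaves it undecided.

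Other splits of the arrays were counted for each comparison. With 4 ways of turning signs against 0, or 10 splits of 3 against 3, the splits are too few for a share under 0.05. Where strains do differ, each other split also moves that difference into the residual spread, which lowers its count. The size of the gap between counts is therefore no measure of support. In each comparison but 1, the real arrangement alone, 1 split, gave as many called probes. The real counts and the highest others were 5 and 1 for RapF, 3 and 0 for RapH, 569 and 70 for RapJ, 1387 and 1 for RapK, 185 and 0 for RapF against RapJ, 94 and 1 for RapH against RapJ, and 94 and 1 for RapK against RapJ. They were 204 and 0 for phrC null and 266 and 0 for phrF null against wild type, 41 and 0 for phrC against phrF null, 15 and 0 for phrC against phrK null, and 66 and 0 for phrF against phrK null. For phrK null against wild type 2 splits gave as many, the real one with 9 and the one that exchanges phrK null replicate 3 with wild-type replicate 1 with 10.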

How the results depend on the processing

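The fits without RapF replicate 1 and RapJ replicate 1 together were chosen after seeing the data. No estimate of a named probe changed sign under any alternative run, and 34 of 47 stayed on their side of the threshold under all of them. Counts of called probes moved more. Scaling arrays to one spread gave 382 for RapF, 399 for RapH, 249 for RapJ, 698 for RapK, 288 for RapF against RapJ, 35 for RapK against RapJ and 19 for phrK null against wild type. Robust moderation gave 9 for RapF and 8 for RapH. Fits of the compared strains alone gave 2 for RapF, 221 for RapH, 107 for RapJ, 819 for RapK, 47, 31 and 31 for RapF, RapH and RapK against RapJ, 66, 82 and 2 for phrC, phrF and phrK null against wild type, 23 for phrC against phrF null and 56 for phrC against phrK null. Without the 2 arrays named above the counts were 83 for RapF, 175 for RapH, 1141 for RapJ, 996 for RapF against RapJ and 535 for RapH against RapJ. As deposited, phrK null gave 26. Leaving out single arrays gave 3 to 10 for RapF, 1 for RapH, 132 to 1092 for RapJ, 880 to 1161 for RapK, 37 to 1010 for RapF against RapJ, 21 to 524 for RapH against RapJ, 52 to 143 for RapK against RapJ, 112 to 234 for phrC null, 117 to 268 for phrF null and 2 to 32 for phrK null against wild type, 23 to 37 for phrC against phrF null, 8 to 25 for phrC against phrK null and 46 to 68 for phrF against phrK null. Some fits had fewer arrays, and otherwise the cause was not tested. The joint Rap fit gave all strains one spread per probe. The median SD over probes was 0.1 in RapH and 0.111 in RapF, but 0.176 in RapK and 0.196 in RapJ. A shared spread favours calls in the more variable strains. RapH had 3 calls and RapJ 569 in the joint fit, but 221 and 107 in fits of single strains. The joint counts therefore do not rank RapH and RapJ by response. RapK had the most calls in both, 1387 and 819.

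The replicate block is in the phr fits because the study describes paired wild-type samples. Deviations from the strain means correlated between arrays of equal number from -0.205 to 0.63 for phrK null and wild type, from -0.009 to 0.395 for phrC null and from 0.014 to 0.099 for phrF null, so the data do not show that the numbers pair the arrays. With no replicate block, phrK null against wild type gave 3 called probes in place of 9, phrC null 172 and phrF null 201. Adding the block to the Rap fits moved no count by over 1.5 times (RapJ 501, RapK 1324). The filters on missing values removed no probe, and the alternatives for gene lists and for cognate Rap and Phr pairs were not run for lack of gene names. Signal over background is not known for these arrays.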

Other observations

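The tests in this part were chosen after the results were seen. The probe with the lowest mean in each rap strain was also the probe lying furthest below the arrays of all other strains, and these 4 probes, WGD8-882, WGD8-884, WGD8-886 and WGD8-887, have identifier numbers within a span of 6. In 10 of 13 comparisons called probes had neighbouring identifier numbers more often than when calls were shuffled over probes. In phrF null against wild type 89 neighbouring pairs were called with the same sign, against a mean of 10 and a highest of 24 in 10000 shuffles (permutation test, one-sided, p = 1e-04, the smallest these shuffles can give; adjusted p = 0.00014 over 13 comparisons). In RapK 351 pairs were found, against a mean of 235. What the identifier order follows is not stated in the files.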
